A study of Caenorhabditis elegans with 9 samples.

How the data were processed

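RNA sequencing of whole Caenorhabditis elegans was carried out on 9 libraries from 3 strains, with 3 libraries per strain. Per the labels' protocols, worms were collected at the late L4 larval stage after growth at 20 °C, total RNA was taken with a column kit, and libraries were made by a standard Illumina procedure. Strain DA1116 carries eat-2(ad1116), strain DCL231 adds acs-22(tm3236), and strain DCL279 carries these alleles together with pmk-1(km25). Groups were read from the genotype in the labels and replicate numbers from the sample titles. The labels do not say that the replicates were separate cultures, so p-values here measure only the spread between these samples, which may be technical.

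The authors deposited 1 table per library of whole-number read counts per WormBase gene, with no normalization. Per the submitters' processing notes, FastQC 0.11.5, TopHat2, HTSeq and DESeq2 were used, the last 3 without a version. The genome build, the annotation release, the strand setting of the counting and the read length are not given in the sources used here. Each table held 46739 genes followed by 5 summary lines that name no gene, which were left out of library sizes and tests. Those lines gave, as shares of all reads, 44.2 to 45.5% in no annotated gene, 0.533 to 0.728% in more than 1 gene and 8.02 to 10.5% aligned to more than 1 place. Because reads aligned to several places were tallied apart, counts of near-identical copies, such as the major sperm protein, vitellogenin, histone, ZK813 and hsp-16 genes, are uncertain. Counts of a gene that overlaps another on the opposite strand are uncertain too, since no strand setting is stated. Among the genes named by the fixed rule given below, only pals-37 had at least 20% of its exon length opposite another gene. Members of families named outside that rule were not checked.

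Reads in genes numbered 8021649 to 10033942 per library, with a median of 8679758, and 17759 to 18957 genes had at least 1 read. No read was found in any library for 22315 genes. Symbols came from a gene name table keyed by the identifiers in the files, which matched 43720 of them, and positions from the Ensembl release 115 annotation of WBcel235, which held 46484. The build used for the deposited counts may differ. No genome sequence was used.

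The main test was edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, fitted once to all 9 libraries, with trimmed-mean scaling, the filterByExpr filter by group and Benjamini-Hochberg adjustment at 0.05 without a fold minimum. It covered 14235 genes, with 6 residual degrees of freedom before moderation and a biological coefficient of variation of 0.184. Replicates differed more in some groups than in others. The chi-square per degree of freedom between pairs of replicates was 4.452 to 6.156 in the triple mutant. It was 12.7 to 26.79 in eat-2 and 14.39 to 38.43 in the double mutant. The fit takes a shared spread per gene, which may be too small in the acs-22 comparison. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. The comparisons were the double mutant eat-2;acs-22 against eat-2, the triple mutant eat-2;pmk-1;acs-22 against the double mutant, and the triple mutant against eat-2. No library of eat-2;pmk-1 was analysed here, so neither the effect of pmk-1 without the acs-22 mutation nor an interaction could be tested. Levels are CPM, the usual scaling of a gene's reads to library size, as mean ± SD over 3 libraries, and log2 fold changes are given ± SE.

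The procedure was tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes. In the acs-22 comparison (13990 simulated genes) it recovered 69% of 2-fold and 95% of 4-fold changes, and 6.82% of its calls were false. In the pmk-1 comparison (13990 genes) these values were 71%, 98% and 3.43%, and for the triple mutant against eat-2 (14000 genes) 71%, 98% and 6.63%. The sign was right for 100% of recovered genes, and 2 of 2 changed lists and 0 of 40 unchanged lists were called in each comparison. Genes were simulated independently, so the list result does not test the preset correlation and lends no weight to the list calls.

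Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. Of 40 lists, 39 had at least 3 tested members, all but the ribosomal RNA list, and adjustment ran over their 117 tests. With the preset correlation 59 tests passed. With a correlation estimated from the residuals 1 passed, the known PMK-1 effectors in the triple mutant against eat-2. Every other camera call therefore rests on the preset value. The fry test takes no preset correlation and tests a list by itself, not against other genes. With it 48 passed, of which 43 were among the 59. Medians, means and test directions differed in sign only in lists that were not called. Where counts of list members called are given, they are over all genes tested and adjusted over the list alone, and for families over all genes only.

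The lists, the comparisons, the alternative analyses except those noted below and the rule for naming genes were fixed before the data were examined. Named were the targeted genes; the 10 genes with the largest rise and the 10 with the largest fall in each of the first 2 comparisons, and 5 of each in the last, among genes past the threshold with a mean CPM of at least 5 and no overlap between groups; up to 4 members per list with the smallest p; and the 10 genes changed most by both acs-22 and pmk-1 in opposite directions. Ratios in groups with 1 to 3 reads carry a 95% counting interval, which covers counting error only. Genes called in both of the first 2 comparisons with opposite signs were set beside the number from independent lists. Their number, and the correlation and covariance of the log2 changes, were set beside 20 simulated data sets in which nothing changed and the double mutant libraries were shared.

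Alternatives were RLE and upper quartile scaling, no count filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, fits of the 6 libraries compared, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, genes of stage-linked lists left out, double mutant libraries split between comparisons and, for lists, an estimated correlation and fry. A covariate of stage-linked expression and the removal of 2 libraries that lay apart from their groups were added after the data were seen. These 2, the fold minimum and the removal of stage-linked lists were run for counts of genes and not for single genes or lists. The spread between replicates was checked for repeated libraries, and none were found. Positions of overlapping and nested genes were handled with bedtools 2.31.1 and pandas 2.3.3 in Python 3.11.15, exact tests used scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.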

Results

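The data describe gene expression in late L4 worms of 3 genotypes that share the eat-2(ad1116) mutation. The gene eat-2 encodes a subunit of a pharyngeal acetylcholine receptor, and its mutants pump and feed slowly, a common model of dietary restriction. The gene acs-22 encodes an acyl-CoA synthetase related to mammalian fatty acid transport proteins, with a known role in the barrier function of the cuticle. The gene pmk-1 encodes a p38 MAP kinase that drives innate immune gene expression. The libraries, 3 per genotype, came from eat-2, eat-2;acs-22 (the double mutant) and eat-2;pmk-1;acs-22 (the triple mutant), with 8021649 to 10033942 reads in genes per library. On the first principal component, with 45.8% of the variance, the double mutant lay at 43.8 to 58.1, eat-2 at -6.74 to 4.79 and the triple mutant at -56.2 to -48.0. On the second, with 20.8%, eat-2 replicate 1 (54.6) lay apart from the other eat-2 libraries (23.7 and 33.1), and double mutant replicate 2 (-3.91) from the other double mutant libraries (-23.3 and -29.9).

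The targeted genes were examined first. Transcript counts of acs-22 (WBGene00017012, X 8931179 to 8939263 on the plus strand in WBcel235) fell from 132.9 ± 8.59 CPM in eat-2 to 22.3 ± 1.51 in the double mutant and 34.49 ± 4.05 in the triple mutant (SD, n = 3). These are log2 changes of -2.57 ± 0.16 (edgeR adjusted p = 1.08e-07) and -1.94 ± 0.15 (adjusted p = 3.33e-07) against eat-2. The level of acs-22 was higher in the triple than in the double mutant by 0.63 ± 0.15 (adjusted p = 0.00652). For pmk-1 (WBGene00004055, IV 8148794 to 8151266, plus strand) the levels were 22.9 ± 1.91, 19.68 ± 4.8 and 28.3 ± 2.0 CPM in eat-2, the double and the triple mutant. No comparison passed the threshold (0.52 ± 0.19 between triple and double mutant, adjusted p = 0.0553). A count over the whole gene does not check a partial deletion, so the pmk-1 label rests on the strain record. The transcript of eat-2 (WBGene00001133, II 14166878 to 14171658, minus strand), a gene mutant in every group, had 0 to 4 reads per library and was not tested.

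**Figure D1:**
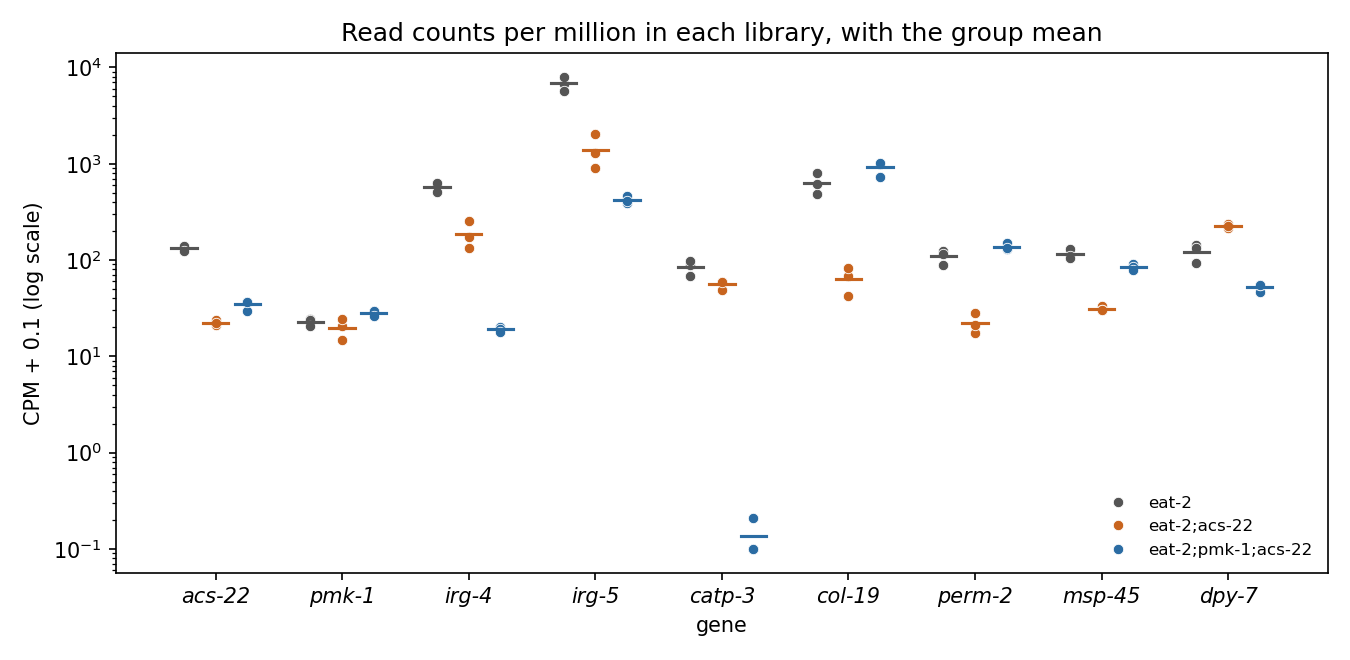
CPM (read counts scaled to library size; log scale, 0.1 added) of 9 genes, 1 point per library and a bar at the group mean of 3 libraries, for eat-2 (grey), eat-2;acs-22 (orange) and eat-2;pmk-1;acs-22 (blue). The 3 eat-2 libraries lie near 133 CPM for acs-22 and the mutants at 22.3 and 34.5, while catp-3 drops from 55.7 to 0.036 CPM between the double and the triple mutant and col-19 dips from 638 to 64.1 and returns to 915.

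The first comparison, of the double mutant with eat-2, asks what the acs-22 mutation changes in eat-2 animals. Sperm and eggshell genes were lower in the double mutant, while pharyngeal muscle, furrow collagen and neuropeptide genes were higher. All of these list calls were lost with an estimated correlation. In the order given, they then stood at adjusted p = 0.248, 0.237, 0.209, 0.494 and 0.196. With fry they passed, at adjusted p = 0.00143, 0.00143, 0.00297, 0.0297 and 0.0025. Of 79 tested sperm genes, 54 fell and none rose (59 fell adjusted over the list alone), with a median log2 change of -1.27 and quartiles of -1.58 and -0.72. The major sperm protein gene msp-45 went from 115.2 ± 13.98 to 31.24 ± 1.58 CPM (-1.88 ± 0.15, adjusted p = 1.06e-06). Likewise msp-113, msp-38 and ssp-10 fell by 1.74, 1.83 and 2.01 on the log2 scale. Of 26 oocyte and eggshell genes, 24 fell (25 adjusted over the list alone; median -1.18). Among them were the eggshell permeability barrier genes perm-2 (-2.31 ± 0.19) and perm-4 (-2.14 ± 0.20) and the RNA-binding regulators puf-5 and pos-1. The sperm list was lower at a camera adjusted p of 1.17e-29 (adjusted p = 0.248 with an estimated correlation) and the eggshell list at 1.09e-17 (adjusted p = 0.237 with an estimated correlation). Germ cell and meiosis genes did not move with them. In that list 1 of 23 members, the cyclin gene cyb-1, fell (-0.98 ± 0.16; also 1 adjusted over the list alone), the median was -0.07 and the list was not called (adjusted p = 0.345).

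Cuticle collagens moved in both directions. Of 142 tested, 60 fell and 29 rose (66 and 36 adjusted over the list alone), with a lower list overall (adjusted p = 0.000288, and adjusted p = 0.523 with an estimated correlation). The adult collagen gene col-19 fell from 637.5 ± 158 to 64.06 ± 20.4 CPM (-3.31 ± 0.25, adjusted p = 4.92e-07). Genes with similar falls were col-7 (-3.98 ± 0.36), col-8 (-3.95), col-62 (-3.77), col-119 (-3.51), col-20 (-3.46), col-81 (-3.37), col-178 (-3.34) and col-139 (-3.28). Collagens with the smallest p included col-122 (-2.73), col-124 (-2.97) and col-140 (-3.21). In contrast, col-41 rose from 12.78 ± 8.58 to 382.7 ± 104.2 CPM (4.89 ± 0.37, adjusted p = 5.28e-07) and col-54 from 4.879 ± 1.04 to 50.38 ± 4.75 (3.37 ± 0.22). Of the 6 collagens of the annular furrows, 5 rose (6 adjusted over the list alone; list adjusted p = 0.000304, and adjusted p = 0.494 with an estimated correlation). Among these, dpy-7 went from 122.5 ± 27.02 to 226.5 ± 10.5 CPM (0.89 ± 0.17), and dpy-9, dpy-2 and dpy-10 rose by 0.86 to 1.00. In the moulting list 8 of 28 members rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00749, and adjusted p = 0.635 with an estimated correlation). The apical matrix gene fbn-1 was at 1.92 ± 0.31 and the moulting regulator nhr-23 at 0.94 ± 0.19. That list call ended without eat-2 replicate 1 (mean log2 change 0.21, against 0.38). In the list of larval to adult markers, 3 of 10 fell (4 adjusted over the list alone), namely col-19, col-62 and col-7 (adjusted p = 0.0178, and adjusted p = 0.493 with an estimated correlation). Its call ended without eat-2 replicate 2 (mean -1.23) or 3 (mean -1.23), against a mean of -1.28 with all libraries. Yolk protein genes were lower as a list (1 of 6 members fell, 3 adjusted over the list alone; median -1.66; adjusted p = 0.0016, and adjusted p = 0.518 with an estimated correlation), and vit-1 fell by 1.28 ± 0.30. Double mutant replicate 2 stood apart here, with vit-6 at 156.2 CPM against 872.2 and 1301 in the other 2 libraries, and without it the mean of the list was -1.18, against -1.68. Across these groups, the mean log2 CPM of the sperm and eggshell lists, used here as a stage-linked score, was 4.93 ± 0.229 in eat-2, 3.76 ± 0.221 in the double mutant and 4.64 ± 0.0569 in the triple mutant (SD, n = 3). Ribosomal RNA was also lowest in the double mutant but highest in the triple mutant, at 1.684 ± 0.188, 1.197 ± 0.284 and 2.486 ± 0.116% of reads in genes (SD, n = 3; exact two-sided permutation p = 0.1 in each comparison, the smallest possible).

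Tissue and signalling lists that were higher in the double mutant included pharynx, neuropeptides, body wall muscle and neurons. The neuropeptide list holds FMRFamide-like and insulin-like peptide families only. The nlp family (55 tested), examined after the data were seen, was not called in any comparison (camera adjusted p = 0.216, 0.0738 and 0.631). Of 13 pharyngeal genes 9 rose (10 adjusted over the list alone; median 1.05; adjusted p = 1.15e-06, and adjusted p = 0.209 with an estimated correlation). They include the pharyngeal myosins myo-2 (39.88 ± 19.1 to 165.4 ± 70.5 CPM, 2.05 ± 0.32) and myo-1 (1.94 ± 0.32). Of 44 neuropeptide genes 11 rose (17 rose and 1 fell adjusted over the list alone; adjusted p = 7.38e-07, and adjusted p = 0.196 with an estimated correlation), for example flp-11 at 1.21 ± 0.18, flp-18 at 1.22 ± 0.26 and flp-1 at 1.21 ± 0.28. Of 16 body wall muscle genes 6 rose, the same number adjusted over the list alone (adjusted p = 0.000979, and adjusted p = 0.523 with an estimated correlation), for example the giant kinase gene unc-22 (1.31 ± 0.23). Of 23 neuronal genes 3 rose (7 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.518 with an estimated correlation). Epidermal markers (4 of 12 rose, also 4 adjusted over the list alone; adjusted p = 0.0424, and adjusted p = 0.561 with an estimated correlation) were called with a mean log2 change of 0.33. That call ended without any 1 of 5 libraries (mean 0.20 without eat-2 replicate 1, 0.35 without eat-2 replicate 3, 0.32 without double mutant replicate 1, 0.25 without double mutant replicate 3 and 0.33 without triple mutant replicate 3). Intestinal markers were not called as a list (adjusted p = 0.216), although the cathepsin gene cpr-1 rose from 219.7 ± 52.3 to 764.2 ± 35.3 CPM (1.80 ± 0.16).

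Immune and stress genes changed in part. Of 17 effector genes known to need PMK-1, 6 fell (1 rose and 6 fell adjusted over the list alone). The infection response gene irg-5 went from 6835 ± 1181 to 1404 ± 573 CPM (-2.28 ± 0.23, adjusted p = 8.88e-06). Also C32H11.4, irg-4 and dod-24 fell by 1.75, 1.62 and 1.33 on the log2 scale. The list was lower at an adjusted p of 0.025 (adjusted p = 0.518 with an estimated correlation). That call ended without double mutant replicate 2 (mean -0.42, against -0.54). A large fall was in the C-type lectin clec-2 (-5.79 ± 0.52; 10.8 ± 2.85 to 0.172 ± 0.161 CPM). The 99 tested C-type lectins were not called as a list, with 17 higher and 18 lower (18 and 21 adjusted over the list alone; adjusted p = 0.841). Lysozyme and saposin-like genes rose in 6 of 29 cases (9 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.518 with an estimated correlation). The largest were spp-23 at 1.92 ± 0.21 and spp-4 at 1.28 ± 0.16. Genes of the intracellular pathogen response (3 of 16 higher, 4 adjusted over the list alone) were called at an adjusted p of 0.00766 (adjusted p = 0.506 with an estimated correlation). The call ended with genes under a mean CPM of 5 left out (mean 0.39, against 0.78), without eat-2 replicate 3 (0.60) or without double mutant replicate 3 (0.48). Genes of the endoplasmic reticulum stress response rose in 4 of 19 cases (6 adjusted over the list alone; adjusted p = 0.000979, and adjusted p = 0.494 with an estimated correlation). The chaperone BiP gene hsp-4 went from 552.0 ± 21.3 to 1145 ± 94.9 CPM (1.05 ± 0.14, adjusted p = 8.18e-05) and the sensor kinase gene pek-1 rose by 1.18 ± 0.17. Cytosolic heat shock genes rose in 5 of 12 cases, also 5 adjusted over the list alone (adjusted p = 0.00766, and adjusted p = 0.56 with an estimated correlation). That list call ended without eat-2 replicate 2 (mean 0.28, against 0.46).

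Lipid genes split within their lists. The desaturase gene fat-7 fell from 220.8 ± 46.4 to 51.66 ± 7.31 CPM (-2.09 ± 0.18), and its relative fat-6 fell by 0.80 ± 0.18, while fatty acid synthase fasn-1 rose by 0.88 ± 0.19. The lipase gene lipl-1 rose from 6.177 ± 1.68 to 29.08 ± 6.18 CPM (2.23 ± 0.23) and the mitochondrial acyl-CoA synthetase gene acs-2 by 3.07 ± 0.45 to 18.29 CPM. The fatty acid synthesis and desaturation list (1 of 26 higher, 4 lower; 2 and 4 adjusted over the list alone; adjusted p = 0.216), the oxidation and lipase list (7 of 33 higher, 5 lower; 8 each way adjusted over the list alone; adjusted p = 0.759), the acyl-CoA synthetase family (2 of 22 each way; 2 and 3 adjusted over the list alone; adjusted p = 0.812) and the sphingolipid list (3 of 23 each way; 3 and 4 adjusted over the list alone; adjusted p = 0.441) were not called. Among glutathione transferase genes gst-4 fell by 1.62 ± 0.22 and gst-20 rose by 1.37 ± 0.17. Other large rises were in dpy-1 (3.02 ± 0.29), grd-13 (2.56), C16D9.1 (2.502), oac-14 (2.42), R05H10.1 (2.42), ZC116.1 (2.41) and fipr-1 (2.34).

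In all, 830 of 14235 genes were higher and 1183 lower in the double mutant than in eat-2 (14.1%), of which 449 and 775 changed at least 2-fold. The count of higher genes was 548 with only the 6 libraries compared, 502 without eat-2 replicate 1 and 448 without double mutant replicate 1. That of lower genes was 863 with only the 6 libraries compared and 730 without double mutant replicate 1. With the stage-linked score as a covariate, an alternative added after the data were seen, 404 genes were higher and 575 lower, of which 74 and 134 were among those above. The score is built from the sperm and eggshell genes and did not overlap between the double mutant (3.55 to 3.99) and the other groups (4.59 to 5.13), so calls lost with it do not show that stage is the cause. With the fry test the list calls of the intracellular pathogen response, moulting, yolk protein, body wall muscle, neuronal, epidermal and heat shock genes ended in this comparison.

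The second comparison, of the triple with the double mutant, asks what the pmk-1 mutation changes in eat-2;acs-22 animals. All 17 tested effector genes known to need PMK-1 fell (17 adjusted over the list alone), with a median log2 change of -3.47 and quartiles of -5.64 and -3.09. The P-type ATPase gene catp-3 went from 55.7 ± 6.27 CPM to 1 read over 3 libraries, a ratio of 1500 with a counting interval of 268 to 59200. The lectin gene clec-67 fell from 140.7 ± 44.6 to 0.643 ± 0.194 CPM (-7.75 ± 0.34, adjusted p = 1.02e-09), C17H12.8 from 109.9 ± 37.96 to 0.539 ± 0.66 (-7.67 ± 0.47), and the lysozyme gene lys-2 from 340.3 ± 60.03 to 30.8 ± 1.45 (-3.46 ± 0.18). In dod-22, 3 reads remained, a ratio of 102 (34.5 to 496). The list was lower at a camera adjusted p of 1.89e-22 (adjusted p = 0.0636 with an estimated correlation). Of 13 epidermal antimicrobial peptide genes 8 fell (9 adjusted over the list alone; adjusted p = 4.78e-07, and adjusted p = 0.198 with an estimated correlation). Among them were cnc-4 (-5.48 ± 0.40), nlp-31 (-4.02 ± 0.31), nlp-30 (-3.33 ± 0.35) and nlp-29 (-2.85 ± 0.30, to 1.69 ± 0.479 CPM).

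Genes of the intracellular pathogen response were higher. In the intracellular pathogen response list 8 of 16 rose and none fell (10 adjusted over the list alone; median 1.33; adjusted p = 0.000608, and adjusted p = 0.4 with an estimated correlation). They include B0507.8 (2.90 ± 0.46, with levels between 0.392 and 0.638 CPM in the double mutant), pals-39 (1.62 ± 0.30) and the cullin gene cul-6 (1.17 ± 0.24). The list call ended with genes under a mean CPM of 5 left out (mean 0.72, against 1.23). The gene pals-37 was higher by 1.33 ± 0.32, with 39.3% of its exon length opposite anr-30, which rose by 1.92, so its own change is uncertain. The lectin gene clec-60 rose from 3.145 ± 0.989 to 108.2 ± 8.16 CPM (5.08 ± 0.29, adjusted p = 9.86e-09), and lys-4 rose by 1.71 ± 0.15 where lys-8 and lys-7 fell by 1.596 and 1.332. The lectins (30 of 99 higher, 28 lower; 34 and 30 adjusted over the list alone; adjusted p = 0.886) and the lysozyme and saposin-like genes (6 of 29 higher, 7 lower; 7 and 10 adjusted over the list alone; adjusted p = 0.544) were not called as lists, nor were the p38 pathway components (1 of 16 each way, none adjusted over the list alone; adjusted p = 0.717).

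Sperm and eggshell genes were higher again in the triple than in the double mutant. Of the sperm genes 44 rose (47 rose and 1 fell adjusted over the list alone; median 0.81; adjusted p = 4.33e-12, and adjusted p = 0.494 with an estimated correlation), with msp-45 at 1.44 ± 0.15. Of the eggshell genes 21 rose (22 adjusted over the list alone; median 1.15; adjusted p = 4.33e-12, and adjusted p = 0.327 with an estimated correlation), with perm-2 at 2.63 ± 0.19. The collagen col-19 rose by 3.83 ± 0.26 and col-7 by 4.47 ± 0.36. In the whole collagen family 58 of 142 members rose and 46 fell, and the list was not called (61 and 50 adjusted over the list alone; adjusted p = 0.2). All 6 yolk protein genes rose, also 6 adjusted over the list alone, with a median of 3.88 (adjusted p = 4.26e-05, and adjusted p = 0.493 with an estimated correlation). Of these, vit-6 reached 9865 ± 1359 CPM, against 776.6 ± 579 in the double mutant and 3331 ± 326 in eat-2. All 6 furrow collagens fell, also 6 adjusted over the list alone (median -2.40; adjusted p = 1.54e-07, and adjusted p = 0.327 with an estimated correlation), with dpy-7 at -2.11 ± 0.18. Of the moulting genes 19 fell and 2 rose, both counts the same adjusted over the list alone (adjusted p = 7.02e-07, and adjusted p = 0.494 with an estimated correlation). Examples are noah-2 at -1.84 ± 0.21 and mlt-11 at -1.97 ± 0.28. The stage-linked score was 4.64 ± 0.0569 in the triple and 3.76 ± 0.221 in the double mutant (SD, n = 3).

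Of the pharyngeal genes 12 of 13 fell, also 12 adjusted over the list alone (median -2.16; adjusted p = 3.12e-08, and adjusted p = 0.196 with an estimated correlation). They include myo-2 at -2.64 ± 0.33 and tni-4, a troponin gene, at -1.599 ± 0.19. Of the neuropeptide genes 23 of 44 fell and 5 rose (24 and 7 adjusted over the list alone; adjusted p = 4.59e-06, and adjusted p = 0.208 with an estimated correlation), with flp-1 at -2.84 ± 0.31 and flp-17 at -2.59 ± 0.27. Intestinal markers rose in 10 of 16 cases (11 rose and 1 fell adjusted over the list alone; adjusted p = 0.000209, and adjusted p = 0.494 with an estimated correlation). The intestinal GATA factor gene elt-2 rose by 1.13 ± 0.20. Epidermal markers fell in 6 of 12 cases and rose in 1, the same numbers adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.521 with an estimated correlation). Endoplasmic reticulum stress genes fell in 11 of 19 cases (13 adjusted over the list alone; adjusted p = 6.48e-06, and adjusted p = 0.327 with an estimated correlation). The level of hsp-4 fell to 348.4 ± 24.4 CPM (-1.72 ± 0.14). Targets of the oxidative stress factor SKN-1 fell in 9 of 23 cases and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.000153, and adjusted p = 0.327 with an estimated correlation). The largest fall there was in gst-12 (-3.34 ± 0.34). Body wall muscle genes were not called as a list (7 of 16 fell, also 7 adjusted over the list alone; adjusted p = 0.123).

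Of the lipid lists, the fatty acid synthesis and desaturation list and the oxidation and lipase list were higher in the triple than in the double mutant. In the fatty acid synthesis and desaturation list 10 of 26 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.00361, and adjusted p = 0.56 with an estimated correlation). In that list fat-7 rose by 2.43 ± 0.18 and fasn-1 fell by 1.08 ± 0.19. In the oxidation and lipase list 15 of 33 rose and 5 fell (17 and 5 adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.518 with an estimated correlation). Examples are the peroxisomal oxidase gene acox-1.2 at 2.29 ± 0.18 and the carnitine acyltransferase gene cpt-5 at 2.58 ± 0.23. In acdh-2, an acyl-CoA dehydrogenase gene, 2 reads remained in the triple mutant, a ratio of 157 (43.2 to 1310). The sphingomyelinase gene asm-3 rose from 11.82 ± 2.57 to 155.1 ± 16.47 CPM (3.71 ± 0.20, adjusted p = 6.74e-09). Of 45 cytochrome P450 genes 17 rose and 6 fell (18 and 6 adjusted over the list alone; adjusted p = 0.00886, and adjusted p = 0.327 with an estimated correlation), for example cyp-33C5 (2.72 ± 0.28). Large rises were in BE0003N10.6 (0.854 ± 0.646 to 51.58 ± 8.18 CPM, 5.92 ± 0.37), D1014.6 (5.47 ± 0.50) and Y71G12B.18 (5.22 ± 0.58), and also in ZK813.3, ZK813.7 and ZK813.1 (4.52 to 4.90) and C08E3.13 (4.42). In double mutant replicates 1, 2 and 3, D1014.6 stood at 0.106, 0.879 and 0.098 CPM and Y71G12B.18 at 0.106, 0.879 and 0. There ZK813.1 stood at 2.34, 0 and 0 CPM. For these 3 genes 1 library held most of the double mutant reads, so the sizes of their rises are uncertain. Large falls outside the lists were in C17H12.6 (-5.18), srlf-34 (-5.14), idpp-1 (-4.97) and F30H5.3 (-4.70).

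Ribosomal protein genes were lower as a list by a small amount (4 of 80 fell, 3 adjusted over the list alone; median -0.18; adjusted p = 0.000511, and adjusted p = 0.523 with an estimated correlation). Of the 4, rpl-25.2 (-3.37 ± 0.66), rpl-36.A (-3.49 ± 0.68) and rpl-14 (-1.41 ± 0.23) had eat-2 replicate 1 on the side of the triple mutant. In that library rpl-25.2 stood at 115.5 CPM, against a mean of 846.6 in the other eat-2 libraries, 857.8 ± 58.2 in the double and 82.94 ± 9.78 in the triple mutant. Mitochondrially encoded genes were lower (median -0.32; 2 of 11 fell, also 2 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.518 with an estimated correlation).

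In all, 1760 genes were higher and 1611 lower in the triple than in the double mutant (23.7% of 14235), of which 951 and 1080 changed at least 2-fold. With the stage-linked score as a covariate 1174 genes were higher and 1037 lower, of which 609 and 433 were among those above. No list call ended with the fry test in this comparison.

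**Figure D2:**
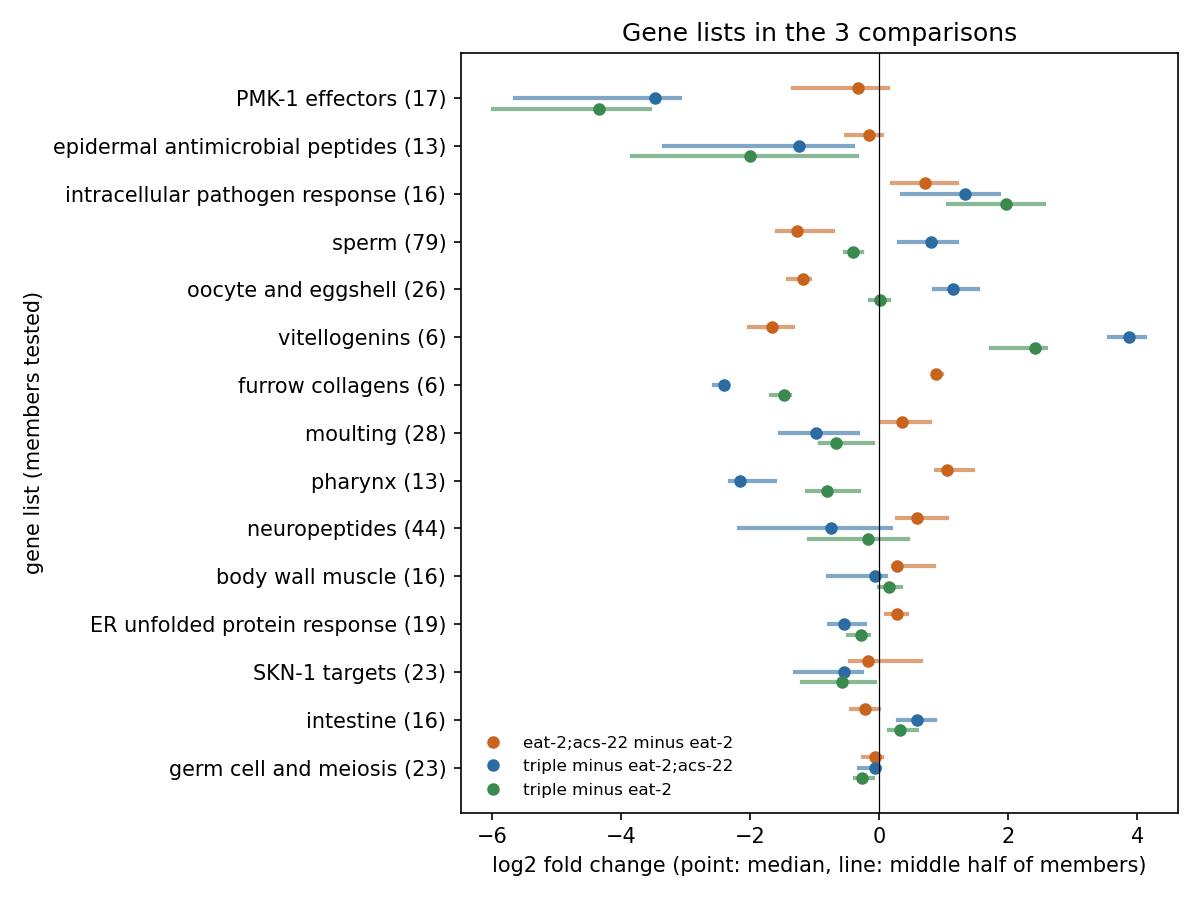
Median log2 fold change of the tested members of 15 gene lists (points) with the middle 50% of members (lines), for the double mutant minus eat-2 (orange), the triple minus the double mutant (blue) and the triple mutant minus eat-2 (green). PMK-1 effectors lie at -0.33, -3.47 and -4.34 in that order, while the eggshell list moves from -1.18 to 1.15 and ends at 0.02.

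The last comparison, of the triple mutant with eat-2, shows what remains when both mutations are present. All 17 PMK-1 effector genes fell, also 17 adjusted over the list alone, with a median of -4.34 and quartiles of -5.98 and -3.56 (adjusted p = 1.33e-34). This was the only list call that held with an estimated correlation (adjusted p = 0.0382 with an estimated correlation). The level of irg-4 was 579.6 ± 61.4 CPM in eat-2 and 19.01 ± 1.03 in the triple mutant (-4.93 ± 0.23, adjusted p = 1.24e-09), with the double mutant between them at 187.9 ± 61.3. The same order held for irg-5, at 6835 ± 1181, 1404 ± 573 and 421.0 ± 35.4 CPM. Epidermal antimicrobial peptides fell in 9 of 13 cases, also 9 adjusted over the list alone (adjusted p = 1.89e-10, and adjusted p = 0.148 with an estimated correlation), and nlp-25 went to 2 reads, a ratio of 81.8 (22.3 to 681).

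Genes of the intracellular pathogen response rose in 10 of 16 cases (13 adjusted over the list alone; median 1.96; adjusted p = 2.74e-10, and adjusted p = 0.196 with an estimated correlation), with B0507.8 at 4.20 ± 0.54 and pals-39 at 1.98 ± 0.31. The level of B0507.8 in eat-2 was very low, between 0.112 and 0.364 CPM, so the size of its rise is uncertain. The lectins clec-60 (6.69 ± 0.34) and clec-52 (3.602 ± 0.623 to 78.41 ± 12.2 CPM, 4.43 ± 0.30) rose, and clec-2 stayed low (-5.28 ± 0.49). Components of the p38 pathway (2 of 16 rose, also 2 adjusted over the list alone) were called at an adjusted p of 0.0116 (adjusted p = 0.622 with an estimated correlation), with nipi-3 at 0.76 ± 0.17. That call ended without eat-2 replicate 1 (mean 0.19, against 0.29). SKN-1 targets fell in 12 of 23 cases and rose in 1 (13 and 1 adjusted over the list alone; adjusted p = 2.53e-06, and adjusted p = 0.211 with an estimated correlation). Among them are gst-38 (-2.26 ± 0.20), gst-4 (-1.90 ± 0.22) and gcs-1, for glutathione synthesis (-1.05 ± 0.14). Of the glutathione transferases, a family that shares several of these genes, 11 of 31 fell, also 11 adjusted over the list alone (adjusted p = 0.00284, and adjusted p = 0.521 with an estimated correlation).

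Among lipid genes, lipl-1 rose from 6.177 ± 1.68 to 55.34 ± 7.20 CPM (3.16 ± 0.23), with lipl-2 at 1.75 ± 0.18, acox-3 at 1.605 ± 0.18 and cpt-5 at 1.93 ± 0.22. In the oxidation and lipase list 12 of 33 rose and 3 fell (14 and 4 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.493 with an estimated correlation). Sphingolipid genes rose in 6 of 23 cases, also 6 adjusted over the list alone (adjusted p = 0.000304, and adjusted p = 0.148 with an estimated correlation). Here asm-3 rose by 3.57 ± 0.20 and the glucocerebrosidase gene gba-4 by 1.07 ± 0.20. Cytochrome P450 genes rose in 12 of 45 cases and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000827, and adjusted p = 0.211 with an estimated correlation). Yolk protein genes rose in 2 of 6 cases, also 2 adjusted over the list alone (adjusted p = 0.00151, and adjusted p = 0.518 with an estimated correlation), with vit-1 at 2.26 ± 0.31. The CPM of vit-1, vit-2, vit-3, vit-4 and vit-6 did not overlap between the triple mutant and eat-2. The spread was estimated over all 9 libraries. Double mutant replicate 2 stood apart in these genes, with vit-4 at 1.13 CPM against 41.66 and 78.41 in the other double mutant libraries. Intestinal markers rose in 3 of 16 cases (6 adjusted over the list alone; median 0.33; adjusted p = 0.000393, and adjusted p = 0.512 with an estimated correlation), with cpr-1 at 2.65 ± 0.17. The desaturation list (5 of 26 rose and 1 fell; 10 and 1 adjusted over the list alone) was called at an adjusted p of 0.0173 (adjusted p = 0.635 with an estimated correlation). That call ended without eat-2 replicate 1 (mean 0.19, against 0.23).

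For the eggshell genes 0 of 26 passed the threshold in either direction with edgeR, also 0 adjusted over the list alone (median 0.02; list adjusted p = 0.886). Of the sperm genes 7 of 79 were lower (6 adjusted over the list alone; median -0.40; adjusted p = 5.23e-08, and adjusted p = 0.518 with an estimated correlation). All 6 furrow collagens fell, also 6 adjusted over the list alone (median -1.47; adjusted p = 7.16e-07, and adjusted p = 0.347 with an estimated correlation), with dpy-3 at -2.06 ± 0.29. Moulting genes fell in 10 of 28 cases (1 rose and 13 fell adjusted over the list alone; adjusted p = 0.000393, and adjusted p = 0.536 with an estimated correlation), with mlt-10 at -1.59 ± 0.23. Of 13 pharyngeal genes 4 fell (5 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.41 with an estimated correlation). That list call ended with genes under a mean CPM of 5 left out (mean -0.52, against -0.74). Neuronal genes were higher (2 of 23 rose, also 2 adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.518 with an estimated correlation). Endoplasmic reticulum stress genes (6 of 19 fell and 1 rose; 7 and 1 adjusted over the list alone) were called at an adjusted p of 0.00519 (adjusted p = 0.518 with an estimated correlation). That call ended without eat-2 replicate 2 (mean -0.18, against -0.27). Ribosomal protein genes were lower (median -0.17; 3 of 80 fell, 1 adjusted over the list alone; adjusted p = 0.000209, and adjusted p = 0.518 with an estimated correlation). The 3 were rpl-14, rpl-25.2 and rpl-36.A, in which eat-2 replicate 1 resembled the triple mutant. The call of rpl-25.2 ended without eat-2 replicate 2 (-2.55), and so did that of rpl-36.A. The stage-linked score differed by less than in the other comparisons (4.93 ± 0.229 against 4.64 ± 0.0569, SD, n = 3, exact two-sided permutation p = 0.2). That score leaves out the yolk, furrow collagen and moulting lists, with medians of 2.41, -1.47 and -0.67 here. It does not show that these groups were alike in stage.

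In all, 726 genes were higher and 830 lower in the triple mutant than in eat-2 (10.9%), of which 313 and 539 changed at least 2-fold. The count of higher genes was 453 among genes with a mean CPM of at least 5 and 415 with the stage-linked score as a covariate (331 of them among those above). It was 381 without eat-2 replicate 3, and 294, 357 and 382 without triple mutant replicates 1, 2 and 3. It rose to 989 with only the 6 libraries compared and to 1042 without double mutant replicate 2. The count of lower genes was 438 without triple mutant replicate 1 and 950 without double mutant replicate 2. With the fry test the list calls of p38 pathway, moulting, desaturation, yolk protein, sperm, neuronal, heat shock, autophagy and histone genes ended in this comparison.

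A further question was how many genes changed by the acs-22 mutation changed back when pmk-1 was also mutated. Of the 2013 genes called in the first comparison, 1293 (64.2%) were called in the opposite direction in the second, against 240.23 from independent lists, and 50 in the same direction, against 236.5. Because both comparisons use the double mutant libraries, the numbers from independent lists are not a proper reference. Of the 1293, 1079 were not called between the triple mutant and eat-2, 189 had passed beyond eat-2 and 25 remained on the side of the double mutant. Of the cuticle collagens 75 of 142 changed back (48 lower then higher, 27 higher then lower), of the sperm genes 44 of 79 and of the eggshell genes 21 of 26, against 1293 of all 14235 genes (one-sided Fisher exact tests over 39 lists, adjusted p = 3.03e-39, 2.02e-24 and 6.26e-17). These tests take genes as independent and use comparisons that share libraries, so their p-values are too small by an unknown amount. In the first comparison the camera calls of these lists were lost with an estimated correlation (adjusted p = 0.523, 0.248 and 0.237). Among genes with a mean CPM of at least 5 over the 9 libraries, those with the largest changes in both comparisons were col-7, col-8, col-62, col-41, col-119, col-20, col-81, col-178, col-19 and ZK813.3. None of the 17 PMK-1 effectors, 13 epidermal antimicrobial peptides or 16 intracellular pathogen response genes changed back in this sense. Only members called in the first comparison could do so, which were 6 effectors, 1 peptide (all lower) and 3 pathogen response genes (higher). The effectors were listed because they need PMK-1, so a rise on its loss was unlikely from the start, and their absence here carries no weight.

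The double mutant libraries enter both comparisons, which by itself makes the changes correlate negatively. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated at r = -0.64, against a mean of -0.50 in 20 simulated data sets without effects, and their covariance was -0.41, against -0.046. With the double mutant libraries split so that none was shared, r was -0.54 to -0.39 and the covariance -0.42 to -0.32. The simulated mean of -0.50 belongs to shared libraries and is not a reference for these splits, for which no sets were simulated. The number of genes changed back was then 408 to 823, but each split leaves 1 double mutant library alone in a comparison, with the spread taken from the other libraries. In the simulated data sets 0 to 1 genes were called in both comparisons with opposite signs (mean 0.05). Nothing changed in those sets, so they do not show how many of the 1293 owe their call to the shared libraries. That share was not measured. The number of genes changed back was 812 without double mutant replicate 1 and 859 with the stage-linked score as a covariate, of which 152 were among the 1293.

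**Figure D3:**
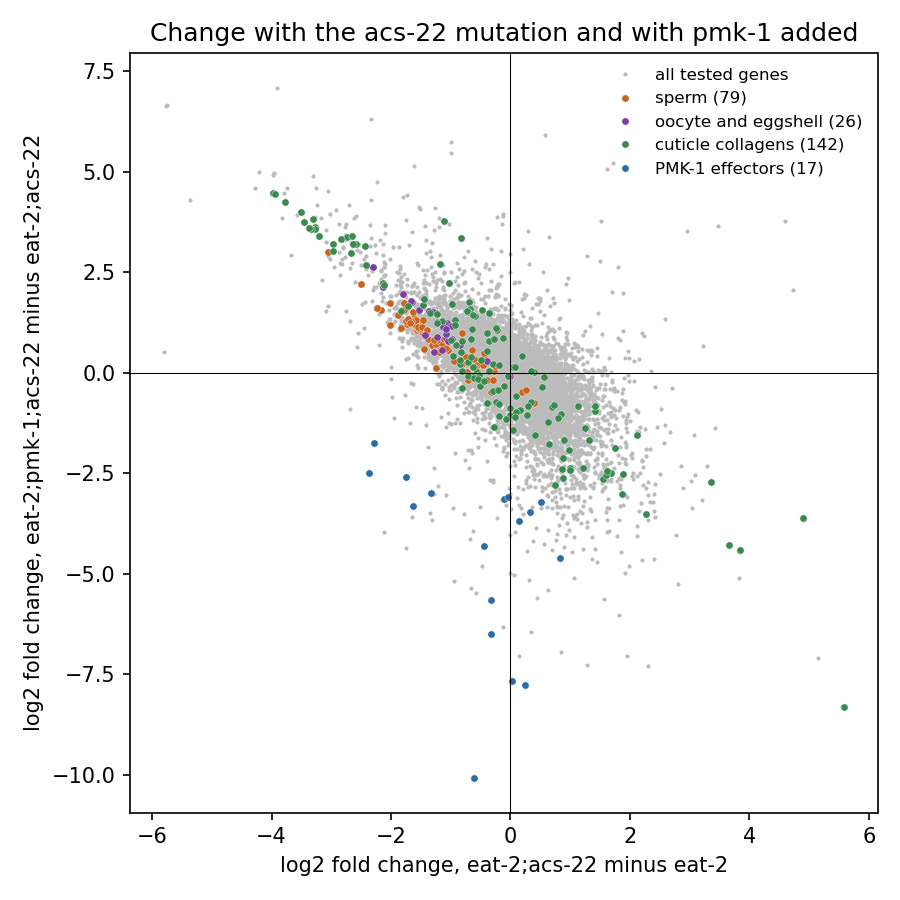
Log2 fold change of the 14235 tested genes between eat-2;acs-22 and eat-2 (horizontal axis) and between eat-2;pmk-1;acs-22 and eat-2;acs-22 (vertical axis), with 4 gene lists in colour. Sperm (79), eggshell (26) and many cuticle collagen (142) genes lie along the falling diagonal of opposite changes, while the 17 PMK-1 effectors lie below it, with a median of -3.47 on the vertical axis.

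Some lists were called in none of the comparisons, several of them with members that moved in both directions. In the 3 comparisons in the order given, there was no call for osmotic stress genes (adjusted p = 0.94, 0.301 and 0.216), fatty acid binding proteins (0.214, 0.886 and 0.2), the acyl-CoA synthetases (0.812, 0.751 and 0.947), DAF-16 targets (0.152, 0.94 and 0.214), UDP-glucuronosyltransferases (0.446, 0.751 and 0.214), the mitochondrial stress response (0.211, 0.2 and 0.886) and F-box families (0.799, 0.849 and 0.758). Single members of these lists did change. In the second comparison hmit-1.1, an inositol transporter gene, rose by 2.49 ± 0.25, far-3 fell by 3.29 ± 0.36, ugt-44 fell by 2.54 ± 0.17 and ugt-6 rose by 2.24 ± 0.23. The small heat shock gene sip-1 fell by 1.76 ± 0.24 in the first comparison and rose by 1.51 ± 0.24 in the second. Between the triple mutant and eat-2, heat shock (adjusted p = 0.0303), autophagy and lysosome (0.0227), histone (0.0294) and neuropeptide (0.0491) lists passed with the preset correlation. In the same order these gave adjusted p = 0.631, 0.56, 0.523 and 0.518 with an estimated correlation. Each of these 4 calls ended when single libraries were left out. Mean log2 changes were then 0.29 and 0.39 for heat shock without triple mutant replicate 2 and eat-2 replicate 2 (0.44 with all). They were 0.20 for autophagy without eat-2 replicate 1 (0.22 with all), and 0.10, 0.16 and 0.20 for histones without triple mutant replicate 1, eat-2 replicate 3 and double mutant replicate 3 (0.24 with all). For neuropeptides they were -0.54 to -0.41 without any 1 of 6 libraries (-0.48 with all). With genes under a mean CPM of 5 left out the heat shock (mean 0.35), histone (0.14) and neuropeptide (-0.26) calls ended too, and with RLE scaling the neuropeptide call (-0.48).

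The other lists without a call are these. In the first comparison they were p38 pathway components (adjusted p = 0.0939), epidermal antimicrobial peptides (0.256), SKN-1 targets (0.685), cytochrome P450 genes (0.772), glutathione transferases (0.341), autophagy and lysosome genes (0.128), ribosomal proteins (0.75), mitochondrially encoded genes (0.231) and histones (0.748). In the second they were larval to adult markers (0.2), sphingolipid genes (0.0774), germ cell genes (0.784), neurons (0.94), glutathione transferases (0.154), heat shock (0.751), autophagy (0.74) and histones (0.214). In the last they were C-type lectins (0.92), lysozymes and saposins (0.078), cuticle collagens (0.216, with 21 of 142 higher and 41 lower, and 31 and 47 adjusted over the list alone), larval to adult markers (0.977), germ cell genes (0.2), body wall muscle (0.2), epidermis (0.2) and mitochondrially encoded genes (0.0506).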

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

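The tests of stage, germ cell number, scaling and tissue share described here were chosen only after the data were seen, while the tests of strand, introns and reads spread over the genome were set before.

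Reads in no annotated gene nearly equalled reads in genes in every library, at 0.983 to 0.995 of them. An unstranded library counted with a strand setting, in which about every other read would be lost, may explain this. In 10 genes nested antisense inside a host gene, the median ratio of reads per kb to the host was 1.148 (quartiles 0.447 to 2.38), as that cause predicts, and it was 1.199 in 30 genes when the minimum for the host was lowered after seeing the first value. The rank correlation of nested and host genes was only 0.127, so this evidence is weak. Reads from introns could do the same, but the median ratio to the host exons was 0 for 52 genes that lie within introns. Reads spread over the genome would need 87.4 reads per kb, and the median of 7305 isolated noncoding genes was 0. The setting itself is not given, so the cause stays open, and a loss shared by all libraries would leave the comparisons unchanged except at overlapping genes.

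Sperm and eggshell genes were lower in the double mutant and higher again in the triple mutant. Scaling is argued against, because 1 factor per library moves all genes alike, and the median of the sperm list lay at -1.292 from that of the ribosomal protein genes. Fewer germ cells is argued against by a median of -0.074 for germ cell genes. Collection of the double mutant at an earlier point of the L4 stage may be the cause and stays open. Of the stage-linked lists used for this test (yolk, furrow collagen and moulting genes), 3 of 3 had the sign it predicts. However, none of these calls held with an estimated correlation. The cuticle collagen and larval to adult marker lists, also linked to stage, were not used in this test (medians -0.39 and -0.15). Any difference in stage follows genotype in these libraries, so slower development with the acs-22 mutation and a different time of collection cannot be told apart.

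Known PMK-1 effector genes were far lower in the triple mutant, as loss of the kinase may cause. A smaller share of intestine is argued against, as intestinal markers were at 0.327 against eat-2. A difference in stage stays open, because the triple mutant lay between the double mutant and eat-2 in only 1 of the 5 stage-linked lists used. Against eat-2 the eggshell median was 0.02, but sperm (-0.40), furrow collagen (-1.47), moulting (-0.67) and yolk (2.41) medians differed. The part of the fall seen with the acs-22 mutation alone, as in irg-5, could reflect lower p38 activity or stage. Its list call ended without double mutant replicate 2 (mean -0.42). In that comparison 6 of the 17 effectors fell and 11 were not called. Neither clec-67 (93.43 to 137 CPM in eat-2, 93.03 to 181.4 in the double mutant) nor lys-2 (232.4 to 293, then 295.7 to 408.5) fell. A general loss of p38 activity is therefore not shown.

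Reads aligned to more than 1 place made up 10.42% of all reads in the triple mutant (10.26 to 10.53), above every eat-2 library (8.86 to 10.03; exact two-sided permutation p = 0.1, the smallest possible), and they were not used here. The share of ribosomal RNA among reads in genes also differed, at 1.684% in eat-2, 1.197% in the double and 2.486% in the triple mutant.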

How the results depend on the processing

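Of 403 named gene results that passed, 323 kept their call under every scaling, filter, test and library removal run for them, and of 59 list calls 1 did; none of these reversed. The covariate, which is built from the sperm and eggshell genes and nearly confounded with genotype, the 2-fold minimum and the removal of 2 libraries together were run for counts of genes only. Higher genes in the acs-22 comparison numbered 548 with only the 6 libraries compared, 404 with the stage-linked covariate, 449 with a 2-fold minimum and 448 (without double mutant replicate 1) to 879 with 1 library left out. Lower genes numbered 575 with the covariate, 775 with the 2-fold minimum and 730 (without double mutant replicate 1) to 1323. In the pmk-1 comparison 951 were higher with the 2-fold minimum and 1037 lower with the covariate, and with 1 library left out 1260 to 1949 were higher and 1194 to 1766 lower. Between the triple mutant and eat-2, higher genes numbered 453 with a mean CPM of at least 5, 415 with the covariate, 313 with the 2-fold minimum and 294 (without triple mutant replicate 1) to 1042, and lower genes 539 with the 2-fold minimum and 438 (without triple mutant replicate 1) to 950. Genes changed back numbered 859 with the covariate, 717 with the 2-fold minimum and 812 (without double mutant replicate 1) to 1314. They were not counted in fits of only the 6 libraries compared. The correlation was -0.391 and -0.4087 with separate double mutant libraries and -0.6824 to -0.6108 with 1 library left out. The log2 change of acs-22 was then -2.628 to -2.528 and the lists called 56 to 63. With an estimated correlation 1 list was called. With the replicate number as a block, the counts were 641 and 1008, 1527 and 1433, and 490 and 647, with 1079 changed back and r at -0.6427. Libraries of the same number gave no sign of sharing a batch (correlations of deviations -0.306 to 0.0703). Across numbers the highest were 0.291 (eat-2 replicate 2, double mutant replicate 3) and 0.268 (eat-2 replicate 1, double mutant replicate 2). No block for such pairs was fitted. Without eat-2 replicate 1 and double mutant replicate 2 together, 1204 changed back.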

Other observations

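Families of genes that share a symbol prefix, 153 of them in 459 tests, were examined only after the data were seen; 33 tests passed with the preset correlation and 0 with an estimated one (adjusted p = 0.997 with an estimated correlation). Cadherin genes were higher in the double mutant than in eat-2, with 6 of 9 members up (median 1.14, adjusted p = 0.001), among them cdh-7 (1.41 ± 0.20), cdh-1 (1.64) and cdh-10 (1.36). Carboxylesterase genes were higher in the triple than in the double mutant, with 17 of 27 up (median 0.73, adjusted p = 3.17e-05), for example cest-10 (1.93) and cest-1.1 (1.32). In the same comparison the srlf family (9 of 14 lower, median -1.36, adjusted p = 0.000499; srlf-34 at -5.14, srlf-3 at -2.53) and the idpp family (9 of 14 lower and 1 higher, median -1.59, adjusted p = 0.00195) were lower. The math family was higher (9 of 17 higher, 1 lower; median 1.00, adjusted p = 0.00688), and 11 of 11 nspc genes were lower (median -1.69), although these are near-identical copies with uncertain counts.

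In rpl-25.2, rpl-36.A and rpl-14, eat-2 replicate 1 (115.5, 96.22 and 574 CPM) sided with the triple mutant (82.94, 82.51 and 455.8 CPM) and the other eat-2 libraries (846.6, 758.5 and 1254 CPM) with the double mutant. Of 10402 genes, 13 had a gap of more than 1 log2 unit of this kind for eat-2 replicate 1, against 4 and 1 for replicates 2 and 3. The labels do not record how libraries were batched.

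Variants linked to the mutant alleles could raise the share of changed genes nearby. Within 1 Mb of acs-22 the share called was 0.9079 of that on the rest of the chromosome (31 of 227 against 256 of 1702; Fisher exact p = 0.621), and near pmk-1 0.8533 (80 of 377 against 525 of 2111; Fisher exact p = 0.134). A few genes changed by linked variants would not show against the many called elsewhere, so such variants are not excluded. On the X chromosome 32.75% of tested genes were called in the pmk-1 comparison, against 17.34 to 27.85% on the autosomes. Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. The real grouping was the highest in each comparison (1 of 10, with 1411, 3595 and 1881 genes), and the highest other split gave 0.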
